A study of Mus musculus with 15 samples.

How the data were processed

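The deposited table held unnormalised values for 24421 mouse gene symbols in 15 kidney libraries. They were taken to be expected counts, that is, reads assigned to each gene with fractions where a read fitted several, because library totals differed and 79.0% to 83.0% of the values of a library were whole while most others were simple fractions. They were rounded and used as counts. Of the symbols, 23376 (95.7%) matched gene names of GENCODE M21 on GRCm38, which was used here for gene positions and lengths only. Before the expected counts were deposited, the reference was mm10 and TopHat2 2.1.1 and Cuffdiff 2.2.1 were used, per the submitters' processing notes; the role of each in making the counts, the strand setting and the gene annotation were not given in the sources used here. Per the labels, total RNA of wild-type kidney was kept in RNAlater, taken up with RNeasy and made into libraries with a SMARTer stranded Pico kit. As the strand setting was not given, reads of genes that overlap on opposite strands could not be told apart. No mitochondrially encoded gene was in the table, so the share of mitochondrial transcripts was not analysed here, while the ribosomal RNA transcript Rn45s was present.

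Genes were tested where edgeR's filter, with a minimum count of 10, held them as expressed for groups of this size, which left 16752 genes. Library sizes were scaled with TMM, and all 15 libraries entered a single fit with a mean per group in edgeR 4.0.16 (quasi-likelihood test, robust settings) under R 4.3.3. P values were adjusted over the 16752 genes with the Benjamini-Hochberg method and called at 0.05, without a fold change threshold. Levels are given as CPM (counts per 1000000 counts of the TMM-scaled library size) and log2 levels used a prior count of 2. Log2 fold changes are given with a standard error worked back from the test, as the absolute change over the square root of its F statistic. Levels are given with their standard deviation. The groups, comparisons, settings and gene lists were fixed before the data were examined.

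Of 37 gene lists drawn up from general knowledge of kidney biology, 36 had at least 3 expressed members and were tested. They held 724 members, of which 713 were in the table, 3 of them under an older symbol. The lists covered matrix and mesenchyme, nephron segments, immune and other cell types, metabolism, oxidant handling and stress programmes. Each was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. A score per library, the mean of its members' standardised log2 levels in the 12 obstructed libraries, was compared between the diets with an exact permutation test. For 12 libraries in groups of 6 the smallest p this test can give is 0.00216. A position along the obstruction change was also computed for each library, with the sham mean at 0% and the UUO mean at 100%.

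Genes named in the text were chosen by rule, and not every gene that met the rule is named. These were the 10 largest rises and falls past the threshold, without overlap between the groups and with an established symbol. Their mean over the libraries of both groups together was at least 5 CPM. Up to 4 members with the smallest p of each list and a panel of 22 genes fixed beforehand were added. Where fewer than 5 genes passed, the 10 genes with the smallest p were named as not passing. List members that went against their list were named from the same tests.

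Alternatives tried were RLE and upper-quartile scaling, no filter and a stricter filter, removal of ribosomal RNA and haemoglobin genes, DESeq2 1.42.0 and limma-voom with sample weights. Fits with only the 2 groups compared, with each library left out in turn, and with sample codes left out were also run. After counts in olfactory and vomeronasal receptor genes had been seen in 4 libraries, fits with a term for these libraries and fits without them were added. The steps were tested on simulated data with known changes before use. In a simulation on 16752 genes, 80.6% of genes with a 2-fold change and 44.8% of genes with a 1.5-fold change were called between UUO_Si and UUO, and 5.19% of its calls were false. Between UUO and sham 61.2% of 2-fold changes and 86.4% of 4-fold changes were called, with 2.59% false calls. The changed genes were not drawn from those of lowest level, and no differences shared by a set of libraries were simulated. The shares called need not hold for the real data. All columns of the table were used and no library was left out of the values given unless stated. No pair of libraries was a copy of another. The labels do not say more on the animals than the group and replicate, so p values measure the spread between samples. Each code series in the sample names belonged to a single group (RM1 to sham, RM3 and RM6 to UUO, RM4 and RM7 to UUO_Si). What the codes mark was not given in the sources used here. A difference between series of different groups could not be told apart from a difference between groups. Among the obstructed libraries, RM6 and RM7 were exactly those with counts in most receptor genes. Checks on these libraries between the diets were thus also checks on the code series.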

Results

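The data were RNA counts from kidneys of wild-type mice 14 days after surgery. In unilateral ureteral obstruction (UUO) the ureter of a single kidney is tied, which injures the tubules and leads to interstitial fibrosis. The groups were sham surgery on normal diet (sham, n = 3), obstruction on normal diet (UUO, n = 6) and obstruction on a diet with a silicon-based agent (UUO_Si, n = 6). Fine silicon can release hydrogen in water; whether this agent did so was not given in the sources used here. The purpose stated for the series was to learn what the oral agent does to renal transcripts. There was no sham group on the agent, so UUO_Si differed from sham in the operation and in the diet.

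Total counts per library, in units of 1000000 counts, were 5.53 to 8.31 in sham, 11.2 to 15.4 in UUO and 7.75 to 11.5 in UUO_Si. UUO_Si libraries differed from UUO libraries by -3.59 in the same unit (9.44 ± 1.23 against 13.0 ± 1.84; SD, n = 6 each; exact permutation p = 0.00433, adjusted p = 0.0714 over 18 library measures). UUO libraries differed from sham by 5.98 in that unit and by -1.51 percentage points in the share of Rn45s. Each had exact permutation p = 0.0119 (adjusted p = 0.0714), the smallest p that this test can give for 3 against 6 libraries. No library measure passed after adjustment, which does not show that the libraries were alike. On the leading principal component of the 15 libraries, which held 57.6% of the variance, sham lay apart from the obstructed groups. Along the next component (17.3%) the 4 libraries with counts in most receptor genes of sensory neurons lay at -33.7 to -68.7 and all others at 5.08 to 29.4. These were sham replicate 3, UUO replicates 5 and 6 and UUO_Si replicate 6, with 1245, 828, 1281 and 1025 of the 1456 olfactory and vomeronasal receptor genes detected against 101 to 166 in the other 11 libraries. Their summed receptor counts were 10063, 4295, 9884 and 4858, against 2644 to 4809 in the others. UUO replicate 5 thus stood apart in the number of receptor genes detected but not in their summed counts.

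**Figure D1:**
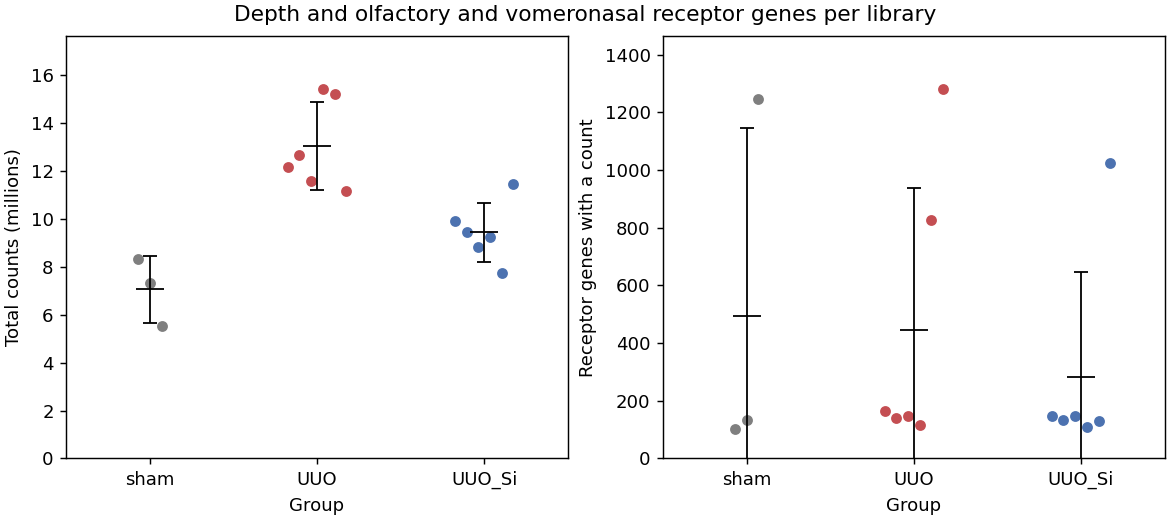
Total counts in units of 1000000 and number of receptor genes with at least 1 count for each library (points), by group, with the group mean and SD (bars). The mean was highest in UUO (13.0 ± 1.84) and 4 libraries held counts in 828 to 1281 receptor genes.

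The comparison of UUO with sham asked what obstruction did to the kidney on the normal diet. All 30 genes of the fibrillar and interstitial matrix list rose, with a median log2 fold change of 3.19. Col1a1, which encodes a chain of collagen I (GRCm38 chromosome 11, 94936224 to 94953042), was at 54.5 ± 19.98 CPM in sham (SD, n = 3) and 2209.7 ± 662 CPM in UUO (n = 6), a 40.7-fold rise. Lrp2, which encodes the proximal tubule's endocytic receptor megalin (chromosome 2, 69424340 to 69586065), fell 13.1-fold from 7037.6 ± 384 to 535 ± 147 CPM. The injury marker Havcr1 (KIM-1; chromosome 11, 46735080 to 46779578) went from 0.726 ± 0.504 to 156 ± 80.2 CPM, with a log2 fold change of 7.67 ± 0.69.

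Among the largest rises after Havcr1 were Timp1 (6.57 ± 0.62), an inhibitor of matrix proteases, Lcn2 (6.24 ± 0.44), which is released by injured distal tubules, Arhgap36 (6.23 ± 0.67) and the matrix gene Ltbp2 (5.92 ± 0.27). Lcn2 went from 3.25 ± 1.46 to 243 ± 102 CPM, 75.4-fold. The protease Mmp7 had 2 counts in all sham libraries together and its ratio of 298 had a 95% counting interval of 82.5 to 2466. The largest falls were Hpd (-6.98 ± 0.56), an enzyme of tyrosine breakdown, Cyp2d12 (-6.94 ± 0.61), G6pc (-6.35 ± 0.37), needed for glucose release, Spp2 (-6.31), Kcnt1 (-6.23), Bhmt (-6.11) and Nccrp1 (-6.05). Egf, made by the distal convoluted tubule and the thick ascending limb, fell from 3557 ± 315 to 55.7 ± 11.9 CPM (-6.00 ± 0.27).

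Mesenchymal genes rose together with the matrix. Col3a1 rose 39.0-fold (71.5 ± 11.7 to 2788 ± 977 CPM), Fn1 by a log2 fold change of 3.76 ± 0.25, Tnc by 4.07 ± 0.20 and Tgfb1 by 2.30 ± 0.13. Of 18 fibroblast, pericyte and myofibroblast markers 14 rose and 4 did not pass (median 1.75), among them Thy1 (4.20), Vim (2.70) and Pdgfrb (2.23 ± 0.14). Acta2, the contractile actin of myofibroblasts and vessels, rose 3.02-fold from 83.8 ± 35.6 to 253 ± 111 CPM, but without the 4 receptor-gene libraries its log2 fold change was 1.15 with adjusted p = 0.0558 in edgeR's quasi-likelihood test. Matrix proteases and inhibitors rose in 17 of 21 members (18 adjusted over the list alone; median 2.34), with Mmp2 (4.52 ± 0.17) and Mmp14 (4.04 ± 0.18), while Timp3 (-0.64) and Plau (-0.70) fell. TGF-beta signalling genes rose in 17 of 21 (1.05), and basement membrane genes in 12 of 20 (13 adjusted over the list alone; 1.08), with Nid1 (2.31) higher and the glomerular chains Col4a3 (-1.94 ± 0.14) and Col4a4 (-1.66) lower. Urothelial and muscle markers rose in 8 of 9 (2.60), a list that did not pass without the 4 receptor-gene libraries (adjusted p = 0.0824 in camera) or with an estimated correlation (adjusted p = 0.386 with an estimated correlation).

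Tubule genes fell along the whole nephron. Of 34 proximal tubule markers 33 fell and 1 did not pass (median -4.10), with Slc34a1, the main phosphate carrier, going from 3142 ± 710 to 89.0 ± 44.9 CPM. Among 20 loop of Henle and distal convoluted tubule markers 17 fell and 1, Cldn19 (0.64), rose (median -1.52). Slc12a3, the thiazide-sensitive carrier, fell from 1551 ± 308 to 165 ± 42.8 CPM and Umod (uromodulin) from 2019 ± 117 to 964 ± 113 CPM (-1.07 ± 0.21). Collecting duct markers fell in 17 of 21 (-1.56; 17 lower and 1 higher adjusted over the list alone), such as Slc26a4 (-2.40) and Rhcg (-1.98). Tubular injury genes rose in 18 of 19 (19 adjusted over the list alone; median 2.99), including Vcam1 (19.6 ± 5.94 to 310 ± 37.4 CPM) and Spp1 (2.99 ± 0.34), and Kl, the anti-ageing hormone Klotho, fell from 407 ± 18.3 to 52.8 ± 15.5 CPM.

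Mitochondrial and peroxisomal metabolism fell with the tubule. All 29 fatty acid oxidation genes fell (median -1.44), for instance Acadm (-2.94 ± 0.19) and the regulator Ppargc1a (-2.14 ± 0.12). Nuclear genes of oxidative phosphorylation fell in 37 of 38 (-1.27), such as Cox5b (-1.83 ± 0.13) and Ndufs1 (-1.48 ± 0.09). Antioxidant enzymes fell in 12 of 20 (13 adjusted over the list alone; -0.67), with Cat (-2.19), Sod2 (-1.77) and Prdx5 (-2.39) lower and Prdx4 (0.55) higher. NRF2 target genes fell in 11 of 24 and rose in 3 (4 adjusted over the list alone; median -0.26), with Osgin1 (-2.52) and Nqo1 (-1.12 ± 0.40) lower and Hmox1 (1.07 ± 0.24), Cbr3 (2.07) and G6pdx (1.18) higher. That list was lost with an estimated correlation (adjusted p = 0.665 with an estimated correlation), and also without UUO replicate 2 (adjusted p = 0.0640 in camera) or UUO replicate 3 (0.0532), and the fall of Nqo1 was lost without sham replicate 1 (adjusted p = 0.0640 in edgeR's quasi-likelihood test) or sham replicate 3 (0.0858). Of 12 genes for NADPH oxidase and oxidant production 7 rose, such as Cybb (11.5 ± 5.29 to 126 ± 9.14 CPM), and Nox4 (-2.30 ± 0.30), a tubular oxidase, and Cyba (-0.85) fell; the list did not pass in camera (adjusted p = 0.0706).

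Macrophage and monocyte markers rose in 22 of 25 (23 adjusted over the list alone; median 3.06), with Lyz2 (32.1-fold), C1qa (3.36 ± 0.18) and Adgre1 (8.48 ± 6.12 to 66.3 ± 15.2 CPM) higher and Mertk (-0.87) lower. All 10 genes of MHC class II presentation rose (3.10), and Cd74 went from 163 ± 25.9 to 1615 ± 264 CPM. Cytokines and chemokines rose in 21 of 26 (1.98), for instance Cxcl1 (5.01 ± 0.38) and Ccl2 (3.61 ± 0.44). Tnf rose by 1.95 ± 0.53, and Il1b rose by 2.02 ± 0.63, a call that was lost without sham replicate 2 (adjusted p = 0.0562 in edgeR's quasi-likelihood test). Complement genes rose in 14 of 18 (2.94), such as C1s1 (3.08), and Cfb fell (-0.89). Interferon-stimulated genes rose in 22 of 26 (1.12), inflammasome and pyroptosis genes in 9 of 14 (1.04), and T and NK cell markers in 10 of 19 (12 adjusted over the list alone; 1.70, and 3.04 without sham replicate 3). Neutrophil markers rose in 2 of 9, Csf3r (1.63) and Il1r2 (2.27), and of 9 B and plasma cell markers Cd79b rose (1.87 ± 0.58).

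Cell cycle genes rose in 23 of 28 (24 adjusted over the list alone; median 1.53), with Top2a (2.93) and Mki67 (2.55 ± 0.23). Targets of p53 and apoptosis genes rose in 16 of 23 (0.77), such as Cdkn1a (1.90 ± 0.17), and 4 fell, namely Mdm2 (-0.38), Fas (-0.55), Sesn2 (-1.13) and Bid (-1.18). Immediate early genes rose in 12 of 17 (1.38), with Klf6 (2.07) and Junb (1.91). Hypoxia and glycolysis genes fell in 12 of 23 (-0.58), with Vegfa at -2.06 and Hk2 at 2.86, and without sham replicate 2 this list was at -0.38 and did not pass (adjusted p = 0.0594 in camera), and with all libraries it had adjusted p = 0.413 with an estimated correlation. For lists given with a single count, the count adjusted over the list alone was the same.

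In all, 9036 of 16752 genes (53.9%) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4609 higher and 4427 lower in UUO. Of the tested genes, 7856 (46.9%) did not overlap between the groups, against 2.38% by chance. Adjusted p was 1.01e-09 for Col1a1, 2.15e-09 for Lrp2, 6.87e-08 for Havcr1 and 5.67e-11 for Egf in edgeR's quasi-likelihood test, and for each of these genes all 6 UUO libraries lay on the same side of all 3 sham libraries. In camera with the preset correlation 27 of 36 lists passed, 17 higher and 10 lower, with adjusted p = 3.14e-16 for the matrix list and for proximal tubule markers. With an estimated correlation 4 lists passed, the tubular injury, TGF-beta, p53 and collecting duct lists, each with adjusted p = 0.0426. The calls of the others were lost, with adjusted p = 0.123 with an estimated correlation for the matrix, macrophage, protease, cytokine and loop lists, 0.156 for fibroblast markers and 0.176 for proximal tubule and fatty acid oxidation. They were 0.169 for inflammasome, 0.181 for complement and MHC class II, 0.225 for interferon and cell cycle, 0.281 for oxidative phosphorylation, 0.314 for immediate early genes and 0.351 for basement membrane. For T and NK cells this value was 0.376, for antioxidant enzymes and urothelial and muscle markers 0.386, for hypoxia 0.413 and for NRF2 targets 0.665. Fry, which does not set a list against all other genes, called 28 of 36 lists. Shares of RNA are measured, so the loss of tubule transcripts raises the share of all others.

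**Figure D2:**
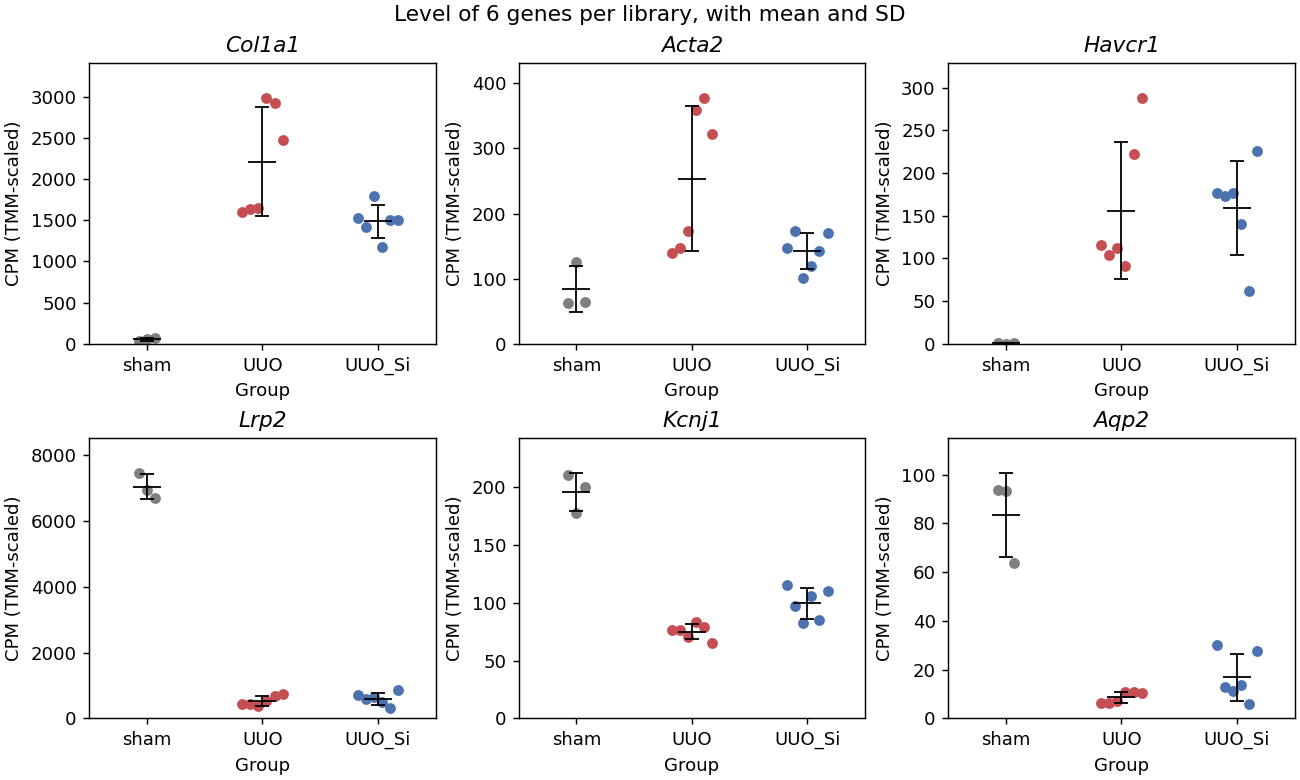
Level in CPM of Col1a1, Acta2, Havcr1, Lrp2, Kcnj1 and Aqp2 in each library (points), by group, with mean and SD (bars). Obstruction separated the groups for Col1a1 (54.5 CPM in sham, 2209.7 in UUO, 1488 in UUO_Si) and the 2 obstructed groups overlapped for most genes shown.

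The comparison of UUO_Si with UUO asked what the agent did in the obstructed kidney. Of 30 matrix genes 28 were below 0 and none passed, with a median log2 fold change of -0.44 (adjusted p = 0.208 with an estimated correlation), which shrank to -0.25 without the 4 receptor-gene libraries. The gap lay between UUO replicates 4 to 6, with Col1a1 at 2470 to 2980 CPM, and the other obstructed libraries, as UUO replicates 1 to 3 (1595 to 1652 CPM) were inside the range of UUO_Si (1173 to 1799 CPM). Col1a1 was at 1488 ± 202 CPM in UUO_Si and 2209.7 ± 662 CPM in UUO (-0.57 ± 0.20; SD for levels, n = 6 each), Col3a1 at 1995 ± 345 and 2788 ± 977 CPM (-0.48 ± 0.20) and Acta2 at 142 ± 28.1 and 253 ± 111 CPM (-0.83 ± 0.26). Of the distal nephron markers, 19 of 20 loop of Henle and distal convoluted tubule genes (median 0.28) and 18 of 21 collecting duct genes (median 0.21) were above 0, with adjusted p = 0.173 and adjusted p = 0.0913 with an estimated correlation. The potassium channel gene Kcnj1 (ROMK) was at 99.5 ± 13.3 and 75.3 ± 6.24 CPM (0.40 ± 0.09) and the water channel gene Aqp2 at 16.9 ± 9.59 and 8.75 ± 2.22 CPM (0.95 ± 0.31). No single gene passed in edgeR, and these lists passed in camera only at the preset correlation.

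The genes with the smallest p, none past the threshold in edgeR, were led by Phlda1, a growth factor-induced gene (chromosome 10, 111506286 to 111508645), at 17.2 ± 1.43 CPM in UUO_Si and 26.3 ± 4.06 in UUO (-0.61 ± 0.11), without overlap between the groups. Sfrp4, which encodes a secreted Wnt modulator (chromosome 13, 19623104 to 19632994), was at 6.59 ± 3.08 and 21.7 ± 10.4 CPM (-1.71 ± 0.36). Col5a1 (-0.57 ± 0.12), Col16a1 (-0.48 ± 0.12), Olfml2a (-0.82) and Susd5 (-1.15) were lower and Kcnj1, Nme7 (0.40) and the small nucleolar RNA Snora23 (0.83) higher. Values of other genes that did not pass were -2.32 ± 0.61 for Actg2, -1.97 ± 0.52 for Cnn1 and -0.92 ± 0.25 for Myh11, and Postn was at 44.7 ± 12.5 and 93.8 ± 54.9 CPM (-1.07 ± 0.32).

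No injury or inflammation gene passed between the diets, which does not show that their levels were equal. Havcr1 was at 159 ± 54.9 CPM in UUO_Si and 156 ± 80.2 CPM in UUO (0.03 ± 0.30), Lcn2 at -0.09 ± 0.23, Spp1 at -0.02, Vcam1 at 0.03, Ccl2 at -0.18, Tnf at 0.12, Adgre1 at -0.14 and Tgfb1 at -0.13 ± 0.09. Il1b was at -0.92 ± 0.43, and cytokines and chemokines had a median of -0.09 with 18 of 26 below 0 (adjusted p = 0.0639 in camera). The median was -0.02 for tubular injury genes (adjusted p = 0.329 in camera), -0.07 for macrophage markers (0.398) and 0.13 for proximal tubule markers (0.105), with Lrp2 at 0.16 ± 0.20 and Slc34a1 at 0.18. Oxidant genes had medians of -0.05 for NRF2 targets (0.238) and 0.05 for antioxidant enzymes (0.521), with Nqo1 at -0.75 ± 0.35, Hmox1 at -0.25 ± 0.18 and Cybb at -0.06.

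Other lists lower with the agent were fibroblast, pericyte and myofibroblast markers (17 of 18 below 0, median -0.35), urothelial and muscle markers (9 of 9, -0.92), erythroid transcripts (8 of 9, -1.13), basement membrane (-0.12), proteases and inhibitors (-0.19), complement (-0.11), TGF-beta signalling (-0.11) and endothelial markers (-0.09). None of these 8 lists kept its call with an estimated correlation: adjusted p = 0.173 with an estimated correlation for fibroblast markers, 0.213 for urothelial and muscle markers, 0.323 for erythroid transcripts, 0.415 for basement membrane and TGF-beta, 0.470 for proteases and 0.712 for complement and endothelium. Fatty acid oxidation (0.10) and hypoxia and glycolysis (0.07) were higher, each with adjusted p = 0.712 with an estimated correlation. Several of these small medians changed in size when a single library was left out. Fatty acid oxidation was at 0.01 without UUO_Si replicate 6 and hypoxia at 0.01 without UUO replicate 2. Without UUO replicate 4 basement membrane was at -0.07, TGF-beta at -0.05 and endothelium at -0.06. Proteases were at -0.12 without UUO replicate 5, and complement at -0.07 without UUO_Si replicate 4 and -0.19 without UUO_Si replicate 6. Adjusted over the list alone, 10 matrix genes, 4 fibroblast markers, 2 urothelial and muscle markers and 7 erythroid transcripts were lower and 1 loop gene higher, against 0 of each over all genes. Among the erythroid genes Hbb-bt was at -1.13 ± 0.36 and Hba-a1 at -1.23 ± 0.47. Hbb-bs and Hbb-b1 had identical values, and Hbb-b1 matched no gene name of GENCODE M21. They were not 2 separate measurements, yet both entered the counts of erythroid transcripts and the summed haemoglobin. Summed haemoglobin was at 58.5 to 73.1 CPM in UUO replicates 1 to 3, inside the 38.6 to 78.3 CPM of UUO_Si replicates 1 to 5, and at 241 to 337 CPM in UUO replicates 4 to 6, so these 3 libraries carried the difference. Malat1 made up 1.37% to 3.49% of UUO replicates 4 to 6 and 6.56% to 7.38% of UUO replicates 1 to 3. In UUO_Si it ran from 1.55% (replicate 6) to 7.81%, so a low share was not particular to these UUO libraries. Without the 4 receptor-gene libraries the erythroid median was -0.69, and the protease (adjusted p = 0.112 in camera), TGF-beta (0.0575) and complement (0.141) lists did not pass.

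By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 16752 genes passed, with 626 at unadjusted p below 0.05 (253 higher, 373 lower) where 837.6 would be expected by chance (393 to 1189 with each library left out) and a smallest adjusted p = 0.874 for Phlda1 (log2 fold change -0.61, all 6 UUO_Si libraries below all UUO libraries). Limma-voom called 0, with 1389 at unadjusted p below 0.05, and DESeq2 called 2, Phlda1 (-0.61, adjusted p = 0.0199 in DESeq2) and Sfrp4 (-1.73, adjusted p = 0.0406 in DESeq2). Of the tested genes, 34 (0.203%) did not overlap between the groups, against 0.216% by chance. Camera with the preset correlation called 13 lists, 9 lower and 4 higher, with adjusted p = 2.53e-18 for matrix, 2.50e-09 for fibroblast markers, 1.01e-08 for loop genes, 1.64e-07 for collecting duct genes, 4.10e-07 for urothelial and muscle markers and 8.56e-07 for erythroid transcripts. With an estimated correlation 0 of the 13 calls held (smallest adjusted p = 0.0913 with an estimated correlation, for collecting duct), and fry called 0 lists. In the exact permutation test on list scores 0 of 36 lists passed (smallest adjusted p = 0.156); the matrix score differed by -0.919 (exact p = 0.0541) and the collecting duct score by 0.637 (exact p = 0.00649), with all 6 UUO_Si libraries on 1 side of the UUO median, which for Col1a1 lay in the gap within UUO.

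**Figure D3:**
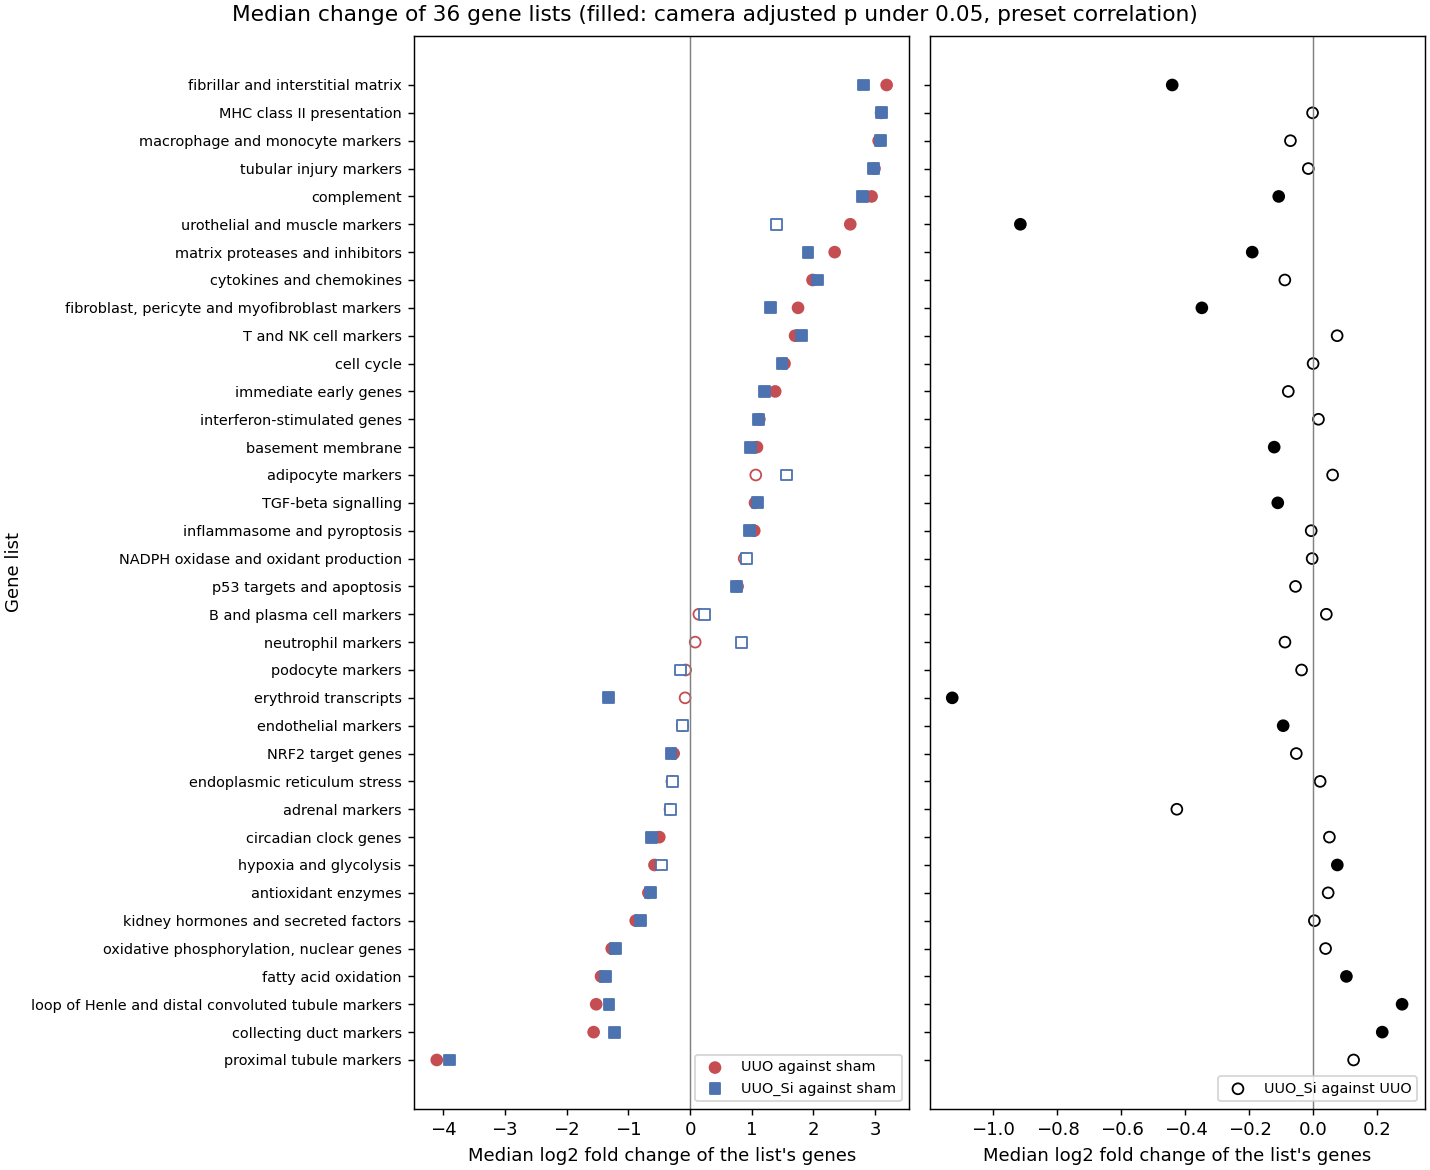
Median log2 fold change of 36 gene lists for UUO against sham (circles) and UUO_Si against sham (squares) on the left, and for UUO_Si against UUO on the right; filled symbols passed camera with the preset correlation. The matrix list lay at 3.19 and 2.81 against sham and at -0.44 between the diets.

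The obstruction change as a whole was also set against the diet. The line used ran from the sham mean to the mean of all 12 obstructed libraries, so it did not depend on which library had which diet. It was scaled to put the sham mean at 0% and the UUO mean at 100%. Along it, UUO_Si libraries lay at 96.7 ± 3.02% (SD, n = 6, range 94.1% to 102%) and UUO libraries at 100 ± 4.51% (94.6% to 108%). The difference was -3.28 percentage points, with 5 of 6 UUO_Si libraries below the UUO median (exact permutation p = 0.169 over 924 splits), inside the range of -4.22 to 4.22 that held 95% of the splits. Without sham replicate 1 it was -0.896 (exact p = 0.855), while it passed without sham replicate 3 (-3.88, exact p = 0.0433) and with changes divided by the SD within groups (-3.59, exact p = 0.0455). Sham libraries ran from -7.26% to 12.2%. The covariance over genes of the diet change with the obstruction change, with the UUO libraries split so that the 2 changes shared none, was -0.0428 (20 splits, -0.0917 to 0.0143). It lay inside the 95% range of -0.0757 to 0.0600 simulated without any group difference. As that simulation held no obstruction change either, its range does not show what covariance would arise without a diet effect, and no conclusion was drawn.

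**Figure D4:**
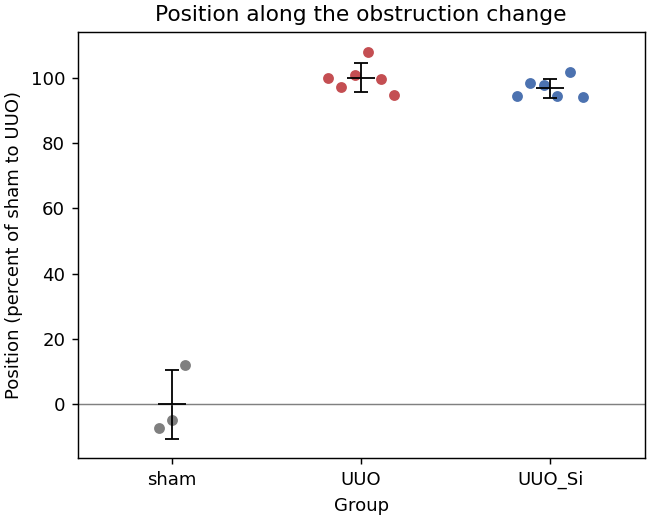
Position of each library (points) along the obstruction change in percent, with the sham mean at 0 and the UUO mean at 100, and group mean with SD (bars). UUO_Si lay at 96.7 ± 3.02% and overlapped UUO.

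The comparison of UUO_Si with sham asked how far obstructed kidneys on the agent stood from unobstructed kidneys on normal diet. All 30 matrix genes rose (median 2.81), with Col1a1 27.4-fold higher (4.78 ± 0.32; 54.5 ± 19.98 CPM in sham, n = 3, and 1488 ± 202 CPM in UUO_Si, n = 6). All 34 proximal tubule markers fell (median -3.90), with Lrp2 11.7-fold lower at 599 ± 183 CPM. Havcr1 rose to 159 ± 54.9 CPM (7.70 ± 0.69), Lcn2 by 6.14 ± 0.44 and Krt20 by 5.76. Cyp2d12 (-7.83 ± 0.69), Hpd (-7.03 ± 0.58), Bhmt (-6.69) and the organic anion carrier gene Slc22a8 (-5.99 ± 0.60) fell most, and Retnla, an alternative activation marker of macrophages with 2 counts in all sham libraries together, had a ratio of 89.3 (24.6 to 739).

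Tubular injury genes rose in 17 of 19 (18 adjusted over the list alone; median 2.97), macrophage markers in 22 of 25 (3.08), cytokines and chemokines in 20 of 26 (2.07), MHC class II genes in 10 of 10 (3.10), cell cycle genes in 23 of 28 (24 adjusted over the list alone; 1.49) and fibroblast markers in 12 of 18 (1.31). Oxidative phosphorylation genes fell in 37 of 38 (-1.20), fatty acid oxidation in 28 of 29 (-1.36), loop genes in 17 of 20 (-1.31) and collecting duct genes in 17 of 21 (-1.22). Col3a1 rose by 4.80 ± 0.32, Fn1 by 3.28 ± 0.24, Tgfb1 by 2.17 ± 0.13 and Adgre1 by 2.86 ± 0.36, and Kl (-2.71 ± 0.23), Umod (-0.72 ± 0.21) and Nqo1 (-1.87 ± 0.41) fell. Acta2 (0.76 ± 0.34, adjusted p = 0.0654 in edgeR's quasi-likelihood test) and Il1b (1.10 ± 0.64, adjusted p = 0.159) did not pass, although without sham replicate 2 Acta2 did (1.18, adjusted p = 0.0175 in edgeR). Both passed in UUO against sham, and tested directly between the diets both had adjusted p = 0.999 in edgeR (log2 fold changes -0.83 for Acta2 and -0.92 for Il1b). Erythroid transcripts fell in 6 of 9 (-1.32), and urothelial and muscle markers, with 4 higher and 1 lower of 9, did not pass in camera (1.40, adjusted p = 0.115).

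In total 8834 of 16752 genes (52.7%) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4558 higher and 4276 lower, with 2.94e-09 for Col1a1, 4.18e-09 for Lrp2 and 7.50e-08 for Havcr1, each with all 6 UUO_Si libraries on 1 side of sham. Camera called 26 lists, 16 higher and 10 lower, with adjusted p = 2.47e-16 for proximal tubule and 2.77e-15 for matrix. None was called with an estimated correlation: adjusted p = 0.0673 with an estimated correlation for tubular injury, 0.0851 for collecting duct, 0.136 for macrophage, cytokine and loop lists, 0.146 for matrix and 0.187 for proximal tubule, fibroblast, fatty acid oxidation and MHC class II. It was 0.218 for cell cycle, 0.282 for oxidative phosphorylation and 0.505 for erythroid transcripts. Fry, which does not set a list against all other genes, called 29 of 36 lists. The operation and the diet both differed between these groups.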

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

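The tests of genomic DNA by coding length, of the sample codes, of the receptor-gene libraries within the diet comparison, of the share of mesenchymal cells and of the diet itself were chosen only after the results were seen.

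Most of the 1456 olfactory and vomeronasal receptor genes had a count in sham replicate 3, UUO replicates 5 and 6 and UUO_Si replicate 6 (828 to 1281), but only 101 to 166 in the other 11 libraries. After all libraries were thinned to the same size, the lowest of the 4 still held 4.30 times as many as the highest other (464 against 108), which speaks against depth, and 1 of the 4, sham replicate 3, lay outside the code series RM6 and RM7, so a round marked by these codes could not be the whole cause. Genomic DNA should give counts that follow gene length: the test set beforehand, on exon length, gave a rho of 0.0646, under the bound that was to speak against genomic DNA, and a test on coding length, 1 of 4 versions computed and chosen after that value was seen, gave 0.226. The bound is in doubt because annotated exons hold long untranslated parts (median 2936.5 against 939 bases of coding sequence in olfactory receptors) and the annotation behind the counts was not given, and with 7.28% of the excess counts in the 10 highest receptor genes the spread was broad, so genomic DNA remains open. Another tissue also remains open, as 12 testis genes had 4.10 and 12 brain genes 3.96 times the counts per kilobase of the receptor genes, yet counts above the level of the other libraries gave ratios of 2.46 and 1.17, under the bound of 3 that was to speak against it for total counts, the highest excess was 1.15 CPM (Akap4) and 2.68 CPM (Mbp), and 1 and 6 of these genes reached 1 CPM in the other 11 libraries.

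The matrix list was lower on average in UUO_Si than in UUO, with Col1a1 at 1488 against 2209.7 CPM. However, UUO replicates 1 to 3 (1595 to 1652 CPM) lay inside the range of UUO_Si (1173 to 1799 CPM). UUO replicates 4 to 6 stood apart with Col1a1 at 2470 to 2980 CPM and haemoglobin at 241 to 337 CPM. Their Malat1 share was 1.37% to 3.49%, a range that also held UUO_Si replicate 6 (1.55%). Compared only within libraries of the same receptor-gene state the score differed by -0.768 (exact p = 0.0212, adjusted p = 0.248), 0.836 of the pooled difference. Without the receptor-gene libraries the median log2 fold change shrank from -0.44 to -0.25, so these libraries could carry a part of the difference. What remained was not told apart from chance, as the score within states did not pass after adjustment. UUO replicate 4, which was not a receptor-gene library, was also among those with high Col1a1. After thinning to equal depth the median log2 fold change was 0.961 of its value (-0.42 against -0.44), but thinning leaves the ratios of abundant genes as they are, so depth was not tested by it and remains open. More renal pelvis tissue in some UUO samples fits, since 9 urothelial markers had a median of -0.68 (score difference -0.871, exact p = 0.0866), for instance Krt5 at 28.3 in UUO_Si and 45.1 CPM in UUO, Psca at 19.1 and 32.2 CPM and Upk1b at 14.9 and 23.7 CPM. As urothelium may also grow in an obstructed kidney and only 2 of these 9 markers were on none of the gene lists, tissue taken and tissue changed were not told apart, and an effect of the diet on fibrosis also remains open, as the matrix score had adjusted p = 0.323 in the exact permutation test over 36 lists.

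No loop of Henle or collecting duct gene passed between the diets, and their list scores, higher in UUO_Si with 4 of 6 and 6 of 6 libraries above the UUO median, had adjusted p = 0.323 and 0.156 in the exact permutation test (camera adjusted p = 0.173 and adjusted p = 0.0913 with an estimated correlation). A smaller share of mesenchymal cells would raise all other cell types alike, and the distal lists differed by 0.235 and the endothelial, podocyte and macrophage lists by -0.0644, a difference of 0.299 (exact permutation p = 0.00866). As the distal lists were picked because they rose and proximal tubule markers (median 0.13, 25 of 34 above 0) were not among the lists set against them, that p does not exclude the explanation, which remains open. The receptor-gene libraries did not account for most of the distal difference, with a distal score difference within the sets 1.01 times the pooled value (0.677 against 0.671, exact p = 0.0238 and 0.0195). Without these libraries the median log2 fold change went from 0.28 to 0.23 for the loop list and from 0.21 to 0.19 for the collecting duct list. Better survival of distal tubule cells on the agent was not tested apart from these and remains a candidate explanation, as does uneven sampling of cortex and medulla.

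Each comparison was also set against regroupings of the same libraries. The real grouping was the only 1 of 84 splits to reach its gene count for UUO against sham (8637 in a fit of the 2 groups, highest other 328) and likewise the only 1 of 84 for UUO_Si against sham (8499, highest other 0). Their list counts were reached by 12 of 84 splits (27 lists, highest other 30) and 17 of 84 splits (26 lists, highest other 29). For UUO_Si against UUO the gene count was 0, which all 100 splits drawn from 462 had to reach, so that count tests nothing (highest other 3070). Of the 100 splits, 67 reached its 13 lists (highest other 23) and 36 reached its 694 genes at unadjusted p below 0.05 (highest other 5943). Splits against sham can keep most sham libraries on the same side and so retain much of the obstruction change. Splits of the obstructed libraries can likewise gather the receptor-gene libraries. List counts of this size were thus reached by other groupings, but these splits do not show what groupings free of any effect would give. The split with 3070 genes put all 3 obstructed receptor-gene libraries on a single side, and within the receptor-gene states 0 genes passed in edgeR's quasi-likelihood test (858 at unadjusted p below 0.05 with a term for the set, 822 without its libraries).

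Over the UUO and UUO_Si groups 130 sets of 6 values were examined, and in 8 of them 1 value stood apart from the other 5, where 6.5 would be expected by chance. Tgfb1 in UUO replicate 2 was at a log2 CPM of 6.23 (others 6.43 to 6.51) and T and NK cell markers in UUO replicate 5 at 1.52 (1.97 to 2.14). Havcr1 in UUO_Si replicate 5 was at 5.95 (7.14 to 7.82), and immediate early genes in UUO_Si replicate 6 at 5.38 (4.61 to 4.88). UUO_Si replicate 6 held 21890 detected genes (18477 to 18642), 1025 receptor genes (108 to 146) and haemoglobin at 148 CPM (38.6 to 78.3). Rn45s made up 4.45% of UUO_Si replicate 3 (2.13% to 2.84%).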

How the results depend on the processing

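The checks with the 4 receptor-gene libraries as a term or left out were chosen only after these libraries were seen, and the bound for the covariance was set after its values were seen. Genes past the threshold for UUO against sham numbered 9036, 7719 to 9302 with each library left out, 8433 to 10061 across other settings, and 4576 with a 2-fold change also required. For UUO_Si against sham they numbered 8834, 7693 to 9012 with each library left out, and 4380 with a 2-fold change also required. Between the diets 0 genes passed in all settings but DESeq2, which called 2 (Phlda1 and Sfrp4). The counts of 27, 13 and 26 lists were 25 to 28, 11 to 16 and 25 to 27 with each library left out; with an estimated correlation they were 4, 0 and 0, and fry called 28, 0 and 29. Of the 13 lists between the diets, endothelium and complement were each lost in 5, TGF-beta in 4, hypoxia in 5 and fatty acid oxidation in 2 of the 15 fits with a library left out. The difference in position along the obstruction change was -3.28, -4.24 to -0.896 with each library left out, with exact p = 0.0433 without sham replicate 3 (-3.88) and exact p = 0.0455 with changes divided by the SD within groups (-3.59). The covariance was -0.0428 and -0.0617 to -0.00615 with each library left out, the smallest without sham replicate 1. UUO_Si and UUO samples share only a replicate number, and blocking on it left 8433, 0 and 8268 genes. The cause was not tested for any result that did not keep its value.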

Other observations

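Clock and hormone genes differed between UUO and sham. Of 18 circadian genes 12 fell and 2 rose (3 adjusted over the list alone; median -0.50), with the clock output genes Usp2 (-2.26), Hlf (-1.99) and Tef (-1.34) lower and Npas2 (1.28) and Bhlhe41 (0.81) higher in UUO than in sham (camera adjusted p = 0.0122; adjusted p = 0.280 with an estimated correlation). Between the diets Usp2 was at 0.51 ± 0.12 and Nr1d1 at -0.45 ± 0.13, each without overlap between 6 and 6 libraries and each past the threshold only when adjusted over the list alone. The sample titles gave the day but no hour of collection. For clock genes a difference in time of day could thus not be told apart from the operation or the diet. Hormones and secreted factors of the kidney fell in 8 of 14 (median -0.88; adjusted p = 0.0328 in camera; adjusted p = 0.386 with an estimated correlation), with Igfbp1 at -3.38, Egf at -6.00 and Hgf, a growth factor of mesenchymal cells, at 1.58, and this call was lost without sham replicate 1 (adjusted p = 0.0690 in camera) or UUO replicate 2 (0.0507).

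Glomerular and vascular genes moved in both directions. Podocyte markers rose in 5 and fell in 5 of 14 in UUO against sham (median -0.07), with Magi2 (-0.93) lower and Cd2ap (0.84) higher. Endothelial markers rose in 5 and fell in 5 of 18 (median -0.12), with Flt1 (-0.94), the receptor of VEGF, lower and Cdh5 (0.99), Pecam1 (0.67) and Ramp2 (1.36) higher. Endoplasmic reticulum stress genes fell in 7 of 18 and rose in 1 (median -0.29), with Herpud1 at -1.95 and Asns at 1.66. Of the 9 genes on the erythroid list only Slc4a1 passed in edgeR, with a fall (-3.51). The list as a whole did not pass (median -0.08, adjusted p = 0.308 in camera), so this fall was not read as a change in blood cells. None of 10 adipocyte or 3 adrenal markers passed in edgeR.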
